A study of Mus musculus with 4 samples.

How the data were processed

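Total RNA of mouse cells was measured on 4 Agilent whole-genome oligonucleotide arrays with 2 colours. Per the labels' protocols, 1 µg of each RNA was amplified and labelled with a commercial Agilent kit. On all 4 arrays the green channel (Cy3) held RNA of the embryonic stem (ES) cell line CGR8.8, and the red channel (Cy5) held RNA of mouse embryonic fibroblasts (MEFs, 2 arrays) or of an induced pluripotent stem (iPS) cell clone (2 arrays). The labels call the 2 arrays of each group biological replicates and do not say whether the cultures were separate, so the p-values measure the spread between these samples, which may be partly technical.

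Per the file headers, spots were read by the authors with Agilent Feature Extraction 10.5.1.1 at 5 micron. The deposited files give the mean intensity of each spot and the median intensity of its local background for both channels, not normalized. They also hold processed signals that the scanner software had background-subtracted, detrended and dye-normalized, with a LOWESS smoothing factor of 0.25 per the file headers. The deposited log10 ratio of red over green was made by the same software from the processed signals. The series' table of values was identical to that log10 ratio at each feature (largest difference 0, median 0 on each array), so its scale and direction were known and it was used as an alternative. Coordinates are those of the probes on the genome build mm8, as the array annotation gives them, and were not converted.

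The mean signals were background-corrected with normexp (offset 50) against the local background in limma 3.58.1 (R 4.3.3; files were read with version 1.17.8 of the data.table package) and normalized within each array by loess (span 0.3), with control spots at weight 0. Control spots and spots marked as outliers by the scanner software were left out. The usual order is to fit normexp over all spots and then remove the marked ones, and the design fixed in advance did not name an order. Fitted over all spots, it was governed on the array of MEF replicate 1 by 14 spots with a local background above 500 (the highest was 694663), all of them marked as outliers, and this compressed the ratios of that array. The fit over the unmarked spots was adopted after the counts under both fits had been seen, and the counts under the other fit stand beside the MEF results.

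Spots of a probe were averaged. Of 41174 gene probes, 27725 were well above background in at least 1 of the RNAs on all of its arrays, and 24874 of these had a value on all 4 arrays. A gene was represented by its probe with the highest mean intensity, which left 17244 genes. Names came from a RefSeq gene table where the probe's accession was in it (24375 probes; 12174 tested genes) and otherwise from the array file, where 44 probes bore a name turned into a date by a spreadsheet and 32 of these were named through the accession. Among the 5600 genes with several tested probes, the probes had opposite calls for 21 genes in MEFs over ES cells, 12 in iPS cells over ES cells and 18 in iPS cells over MEFs. Calls differed, with a call on some probes and none on others included, for 1484, 1081 and 1658 genes. Among called genes set by the naming rule and named in the text, another probe lay under 2-fold for B2m, E2f1, Esrrb, Hk1, Lyz2, Map2, Pdgfra, Xist, Ywhaz and Zscan4c in MEFs over ES cells. The same held for Aif1, Col1a1, E2f1, Hoxb2, Pfkp, Prss23, Tbx3 and Thumpd1 in iPS over ES cells, and for Col1a2, Dsp, Lyz2, Myc, Nefl, Sox17, Trp53 and Xist in iPS cells over MEFs.

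A linear model with a coefficient per group was fitted over all 4 arrays with limma's lmFit and eBayes (2 residual and 4.43 prior degrees of freedom). MEFs and iPS cells were each tested as the ratio over ES cells against 0, and iPS cells over MEFs as the difference of the coefficients. The ratio against 0 holds the ES cells' own spread only as far as the ES RNA differed between arrays. Whether that RNA came from separate cultures is not stated. Dyes were not swapped on the arrays used here, so a gene-specific dye effect stays in the ratios over ES cells and cancels only between iPS cells and MEFs. All 4 arrays lay on 1 slide and were read in 1 scan, so the position on the slide cannot be told apart from the group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with at least a 2-fold change. Errors are standard errors of the limma coefficients, and with 2 arrays per group the number of arrays limits the precision. A gene not well above background on every array of a group has only a bound there. Its ratio is given as at least N-fold, from normalized log2 means per channel against the lowest signal well above background, and is open to dye bias. For iPS cells over MEFs it sets the red channels of different arrays against each other without the ES channel, and where it exceeded the fold of the fit (507 of 914 called genes with a dim group) no fold is given.

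The 22 gene lists were tested with camera (preset correlation of 0.01, and again with an estimated correlation), adjusted over the 66 tests. They cover core pluripotency, fibroblast matrix, mesenchymal regulators, epithelial junctions, lineage differentiation, primed epiblast, 2-cell stage, germ cells, imprinted genes, sex-linked genes, the Hox clusters, the cell cycle, cell cycle brakes with the D-type cyclins, chromatin regulators, glycolysis, interferon and MHC class I, LIF and BMP targets, macrophages, endothelium, muscle, neurons and housekeeping. The genes named were set by rule, and a few that it selects are not reported here. For each comparison these were the 6 largest changes per direction among called genes moving the same way on every array, unnamed clones left out, the called list members with the largest changes, and 13 genes always given. Other list members were named as examples after their values were seen. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined; the normexp fit, the crossed pairing and the fit without chromosome 11 were chosen after.

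Tested on simulated log ratios with 17244 genes per comparison, the limma fit called 67 of 67 genes changed by 1.5 on the log2 scale in each comparison over ES cells and 65 of 67 (97.0%) in iPS cells over MEFs. It called 66 of 66 changed by 3 in each comparison, 0 of 67 changed by 0.5, which lies under the fold limit, and 0 of 17044 unchanged genes. The fold limit by itself keeps the last count low. By the adjusted p alone, 7 unchanged genes passed in MEFs over ES cells and 0 in each of the other comparisons. A list of 30 simulated genes shifted by 0.5 had a camera p of 1.16e-56, and 2 of 100 unshifted lists had an unadjusted p under 0.05. The simulated noise had only the replicate spread, and nearly all other genes stood at 0. The measured ratios spread far more across genes (standard deviation 0.996 to 1.145), so this p does not carry over. Genes simulated as independent cannot check the preset correlation, and background correction, normalization and probe choice were not simulated. The alternatives were other background corrections and normalizations, the processed signals, the series' value table, the red channel alone, filters on dim probes, the mean over probes, marked spots kept, another prior, separate fits, a replicate block, each replicate left out, and other thresholds.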

Results

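RNA of MEFs and of an iPS cell clone was compared with RNA of the mouse ES cell line CGR8.8, to ask how the clone's transcripts compare with those of ES cells and of fibroblasts. ES and iPS cells had been grown with leukemia inhibitory factor (LIF) at 1000 IU/ml. The iPS cells were taken 30 days after transduction, and MEFs had been passaged several times. Each of the 4 arrays carried ES cells in green, with MEFs in red on 2 arrays and iPS cells in red on 2 arrays. Between 62.0% and 63.4% of the gene probes were well above background in green and between 61.05% and 63.2% in red. Across genes, the log2 ratios of the replicate arrays correlated at 0.991 (MEF) and 0.994 (iPS), and those of a MEF with an iPS array at 0.0165 to 0.0227. The replicates differed by more than spot noise: among 202 probes printed 10 times, 50.5% (MEF) and 20.8% (iPS) differed beyond it, where 5% would by chance. Values below are log2 ratios ± standard error of the limma fit (n = 2 arrays per group), and the adjusted p of the called genes named by rule lay between 5.02e-09 and 0.000145.

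In MEFs, most measured genes of the pluripotent state were lower than in ES cells, and most of the fibroblast matrix were higher. Zfp42 (Rex1), a marker of undifferentiated ES cells, stood at -6.50 ± 0.065, Sox2 at -4.65 ± 0.048, Pou5f1 (Oct4) at -4.10 ± 0.078 and Nanog at -3.79 ± 0.046. Cavin2, a component of caveolae, stood at 7.67 ± 0.070, Tm4sf1, a membrane protein, at 7.47 ± 0.061, and Lox, which crosslinks collagen and elastin, at 5.94 ± 0.071. Mcm7 (-2.50 ± 0.043) and Mcm2 (-2.38 ± 0.044), which encode parts of the replicative helicase, were lower. Xist, the RNA that silences an X chromosome, was at least 45.7-fold higher in MEFs and not well above background in ES cells, and the Y-linked Ddx3y fell to -1.87 ± 0.046.

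The other largest rises in MEFs were Fibin (6.91 ± 0.044), Clca3a1 (6.38 ± 0.056) and Mgp, a matrix protein that inhibits calcification (6.08 ± 0.046). The other largest falls were Sp5, a transcription factor downstream of Wnt (-5.89 ± 0.044), and Nefl, the light neurofilament (-5.83 ± 0.063). They were followed by Cdh1, E-cadherin (-5.75 ± 0.057), Tdh, threonine dehydrogenase (-5.67 ± 0.060) and Gbp3, an interferon-induced GTPase (-5.22 ± 0.045). Dppa3 (-3.69 ± 0.044) and Esrrb (-2.99 ± 0.046) fell as well. Col1a1, the main chain of type I collagen, rose by 4.32 ± 0.045 and Thy1, a surface marker of fibroblasts, by 4.19 ± 0.056. Klf4 (0.75 ± 0.044, or 1.43 with median centring), Myc (-0.65 ± 0.047) and the imprinted RNA Meg3, named Gtl2 on the array (-0.18 ± 0.064), did not reach 2-fold. The value of Meg3 turned to 0.51 with median centring and to 0.53 with the mean over probes, and its other probes stood at 2.03, 0.29 and -0.02. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19, rose by 2.37 ± 0.18, with 1.93 on the first MEF array and 2.81 on the second. On mm8, the probe of Pou5f1 lies at chromosome 17, 35118388 to 35118448. The probes of other genes lie at chromosome 6, 122679692 to 122679751 (Nanog), chromosome 3, 34843400 to 34843459 (Sox2), chromosome 11, 94767851 to 94767910 (Col1a1), chromosome 12, 110019275 to 110019334 (Meg3) and chromosome X, 99666300 to 99666359 (Xist).

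Of the 26 core pluripotency genes measured, 22 fell in MEFs, 0 rose and 4 were not called (median over all measured members -3.22, camera adjusted p = 6.38e-08, estimated-correlation adjusted p = 0.32). The 34 fibroblast matrix genes moved the other way, 31 higher, among them Col5a2 (5.58 ± 0.050), and 3 not called (median 3.66, adjusted p = 1.44e-12, estimated-correlation adjusted p = 0.31). Among 15 mesenchymal regulators 8 rose, including the homeobox gene Prrx1 (5.87 ± 0.095) and the forkhead gene Foxc2 (4.76 ± 0.056), and 7 were not called (median 1.42, adjusted p = 0.000108, estimated-correlation adjusted p = 0.32). Of 18 epithelial junction genes 17 fell, among them Cldn7 (-4.69 ± 0.046), and 1 was not called (median -3.22, adjusted p = 1.27e-07, estimated-correlation adjusted p = 0.31). Counts adjusted over the list alone were the same for each of the 22 lists in all 3 comparisons. With an estimated correlation none of the 38 list shifts called at the preset correlation held, and the lowest adjusted p was 0.31. That test rests on the 2 residual degrees of freedom and could hardly call any list, so the loss does not show that correlation undoes the shifts. The fibroblast matrix list had an estimated correlation of 0.0065, under the preset 0.01, and lost its call all the same. Over the called lists the estimates ran from -0.071 (macrophages) to 0.30 (core pluripotency), with 0.20 for mesenchymal regulators and 0.17 for epithelial junctions. Where the estimate lies far above the preset, the adjusted p at the preset correlation may be much too small.

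The cell cycle list had 23 of 28 genes lower and only E2f1, a transcription factor of S phase entry, higher (1.30 ± 0.046), with 4 not called (median -1.58, adjusted p = 2.37e-07, estimated-correlation adjusted p = 0.31). The list of cell cycle brakes also holds the D-type cyclins Ccnd1, Ccnd2 and Ccnd3, which promote G1 progression. Of its 17 measured genes 10 rose, including Igfbp7 (3.66 ± 0.057) and these cyclins (2.47, 2.86 and 1.53), and 2 fell, Gadd45b (-2.01 ± 0.046) and Igfbp3 (-1.61 ± 0.051), with 5 not called (median 1.39, adjusted p = 0.0156, estimated-correlation adjusted p = 0.347). Chromatin regulators fell in 13 of 20 cases, led by Dnmt3l (-4.61 ± 0.080) and the DNA methyltransferase Dnmt3b (-4.23 ± 0.048), and 7 were not called (median -1.13, adjusted p = 1.75e-05, estimated-correlation adjusted p = 0.31). Hox genes, which set position along the body axis, rose in 17 of 33 cases, with Hoxc9 at 4.45 ± 0.044 and Hoxa11 at least 20.4-fold higher. Hoxb1 (at least 2.23-fold lower) was among the 3 that fell, while 13 were not called (median 1.03, adjusted p = 0.000114, estimated-correlation adjusted p = 0.31). Of 29 imprinted genes 7 rose, including the growth factor Igf2 (3.18 ± 0.069) and Dcn (3.47 ± 0.046). Another 3 fell, including Phlda2 (-3.34 ± 0.072) and Snrpn (-1.70 ± 0.045), and 19 were not called (median 0.27, adjusted p = 0.644). Lineage genes were split, with 4 of 25 higher, including Zic1 (4.85 ± 0.11) and Pdgfra (2.31 ± 0.049). Another 11 were lower, including T, brachyury (-4.40 ± 0.063) and Cdx2 (at least 11.5-fold lower), and 10 were not called (median -0.40, adjusted p = 0.168).

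Of 10 primed epiblast genes 8 fell, led by Pou3f1 (-4.62 ± 0.046), and 2 were not called (median -3.73, adjusted p = 9.4e-05, estimated-correlation adjusted p = 0.31). Germ cell genes fell in 6 of 21 cases, including the synaptonemal complex gene Sycp3 (at least 12.8-fold lower), and 15 were not called (median -0.56, adjusted p = 0.00173, estimated-correlation adjusted p = 0.31). Muscle genes rose in 7 of 13 cases, including embryonic myosin Myh3 (2.63 ± 0.054), and 6 were not called (median 1.70, adjusted p = 0.0119, estimated-correlation adjusted p = 0.31). Markers of macrophages included 6 higher, with the lysozyme gene Lyz2 at 4.88 ± 0.068 (its other probe 0.63), 1 lower, Cd68 (-1.69 ± 0.050), and 7 of 14 not called (median 0.68, adjusted p = 0.0536). Of 10 endothelial markers 2 rose, including Emcn (5.07 ± 0.060), 2 fell, including Kdr (-1.54 ± 0.046), and 6 were not called, with a median of -0.49 and a mean of 0.16, of opposite sign (adjusted p = 0.446). The interferon and MHC class I list had 2 of 20 higher, including B2m (2.01 ± 0.044), 9 lower, including the immunoproteasome gene Psmb8 (-3.87 ± 0.045), and 9 not called (median -0.61, adjusted p = 0.12). Of 14 LIF and BMP targets 2 rose, including Stat3 (2.81 ± 0.049), 4 fell and 8 were not called (median -0.15, or 0.31 with median centring; adjusted p = 0.765).

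Of 18 glycolysis genes 3 rose in MEFs, including hexokinase Hk1 (2.70 ± 0.044), 3 fell, including the glucose transporter Slc2a3 (-2.54 ± 0.048), and 12 were not called (median 0.50, adjusted p = 0.309). Neuronal genes had 1 of 10 higher, Map2 (1.14 ± 0.047), 5 lower and 4 not called (median -0.77, adjusted p = 0.18). The 2-cell stage list had 2 of 9 higher, including Tdpoz1 (1.22 ± 0.077), 3 lower, including Zscan4c (at least 5.59-fold lower), and 4 not called (median -0.37, adjusted p = 0.168). Sex-linked genes had 1 of 7 higher, Xist, and 2 lower, Ddx3y and Uty (-1.05), with 4 not called (median 0.042, adjusted p = 0.968). That median turned to -0.87 with the stricter filter on dim probes, -0.080 without MEF replicate 1, -0.050 with marked spots kept and -0.0385 with normexp over all spots. Housekeeping genes had 4 of 13 higher, including B2m, 2 lower, including Ywhaz (-2.99 ± 0.061), and 7 not called (median 0.12, or -0.11 with quantile normalization; adjusted p = 0.684). In all, 2413 genes were higher and 2363 lower in MEFs, together 27.7% of the 17244 genes tested, and 14426 genes (83.7%) had an adjusted p under 0.05 at any fold. With normexp fitted over all spots, only 35 were higher and 25 lower, with marked spots kept 153 and 135, and without MEF replicate 1 there were 2467 and 2408. Among genes well above background in both channels of all 4 arrays, the germ cell (median -1.96, adjusted p = 0.148) and muscle (median 1.345, adjusted p = 0.0857) shifts were not called. The lineage, 2-cell stage, interferon and neuronal lists were called with median centring, and the macrophage list under several alternatives. The share of higher calls was 50.5%, and 69.6% with median centring.

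**Figure D1:**
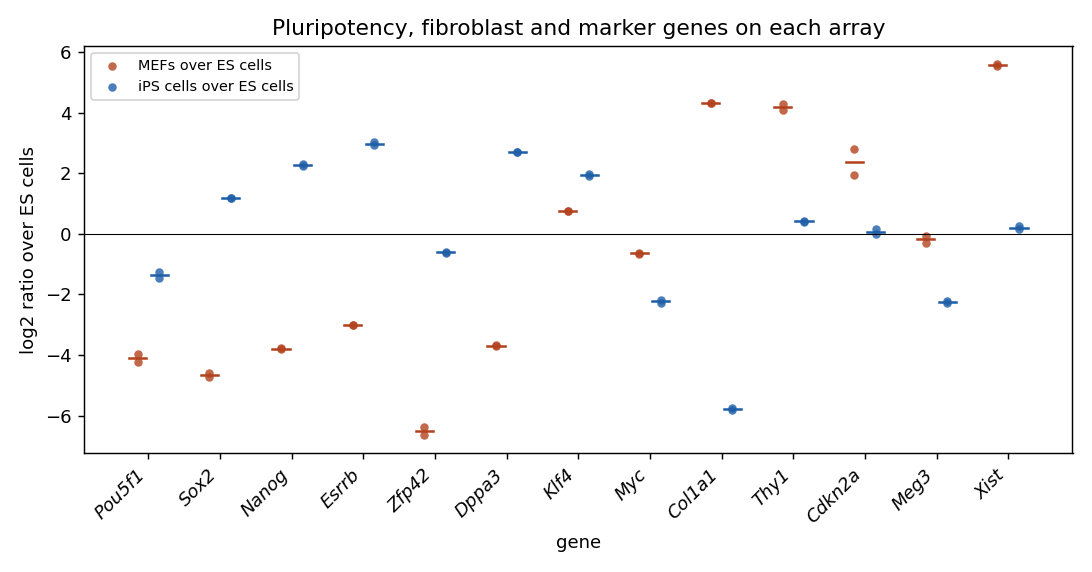
Log2 ratios over ES cells of the 13 genes always named, with a point per array (2 MEF arrays and 2 iPS arrays) and a line at the group mean. Pou5f1 lies below 0 in both groups (-4.10 and -1.35), Nanog below 0 in MEFs (-3.79) and above it in iPS cells (2.27), and Col1a1 above 0 in MEFs (4.32) and below it in iPS cells (-5.77).

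In iPS cells, many genes of the germ line and of the pluripotent state were higher than in ES cells. Lower were 19 of 34 genes of the fibroblast matrix, 16 of 18 of epithelial junctions and 16 of 20 of the interferon and MHC class I list. Dazl, an RNA-binding protein of germ cells, stood at 6.88 ± 0.055, Esrrb at 2.98 ± 0.046, Dppa3 at 2.71 ± 0.044, Nanog at 2.27 ± 0.046 and Sox2 at 1.19 ± 0.048. Pou5f1 was lower, at -1.35 ± 0.078, as was Myc, at -2.22 ± 0.047, while Klf4 was higher, at 1.94 ± 0.044. With marked spots kept, the calls of Esrrb (limma adjusted p = 0.0718), Dppa3 (0.128), Nanog (0.166), Sox2 (0.466) and Pou5f1 (0.365) were lost. Their ratios there were nearly the same, and Dazl, Myc and Klf4 kept their calls. Col1a1 fell to -5.77 ± 0.045, the keratins Krt18 and Krt19 to -4.61 ± 0.046 and -4.75 ± 0.058, and B2m, the light chain of MHC class I, to -3.26 ± 0.044. Zfp42 (-0.60 ± 0.065; its other probe -1.35), Thy1 (0.42 ± 0.056) and Cdkn2a (0.07 ± 0.18) did not reach 2-fold. Xist was not well above background in either cell type.

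The other largest rises were Nlrp4f, a gene of the oocyte (6.23 ± 0.11), Xlr5a (5.96 ± 0.060), Rpl39l, a paralog of a ribosomal protein gene (5.90 ± 0.054), Khdc3, a gene of oocytes and early embryos (5.78 ± 0.071), and Thumpd1 (5.40 ± 0.059). Thumpd1 was also at 4.75 in MEFs, and its second probe stood at -0.03 in iPS cells and -0.49 in MEFs. The other largest falls were the serine protease Prss23 (-7.17 ± 0.045), Gbp3 (-6.79 ± 0.045), caveolin Cav1 (at least 74.6-fold lower), Fndc3c1 (-5.70 ± 0.068) and Irs1, an adaptor of insulin signalling (-5.68 ± 0.044). Several of these probes had a milder partner: the other probe stood at -0.33 for Prss23, -1.24 for Cav1 and -1.23 for Irs1, and the other probes of Col1a1 at -2.98 and -0.49. The probe of Dazl lies on mm8 at chromosome 17, 49745165 to 49745224.

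Among the 26 core pluripotency genes 17 rose in iPS cells, including Tbx3 (3.71 ± 0.051; its other probe 0.62) and Fbxo15 (3.54 ± 0.044). Another 3 fell, including Lin28a (-2.0 ± 0.049) and Pou5f1, and 6 were not called (median 1.63, camera adjusted p = 0.000108, estimated-correlation adjusted p = 0.436). Germ cell genes rose in 19 of 21 cases, including Taf7l (4.41) and the receptor Kit (3.63), while Tdrd1 fell (-1.14 ± 0.062) and Sycp2 (0.59) was not called (median 2.41, adjusted p = 1.27e-07, estimated-correlation adjusted p = 0.31). The 2-cell stage list had 7 of 9 higher, including Zscan4c (4.22 ± 0.072), and 2 not called (median 1.71, adjusted p = 0.000491, estimated-correlation adjusted p = 0.31). Chromatin regulators rose in 8 of 20 cases, including Jarid2 (2.02 ± 0.060) and Dnmt3l (1.91 ± 0.080), and 12 were not called (median 0.86, adjusted p = 0.000959, estimated-correlation adjusted p = 0.31). Of 28 cell cycle genes 4 rose, including E2f1 (1.96 ± 0.046) and the kinase Aurkb (1.32 ± 0.050), and 24 were not called (median 0.32, adjusted p = 0.0108, estimated-correlation adjusted p = 0.31).

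The fibroblast matrix list had 19 of 34 genes lower in iPS than in ES cells, including Thbs1 (-4.71 ± 0.058), 14 not called, and the collagen receptor Ddr2 higher (2.29 ± 0.070; median -1.65, adjusted p = 1.68e-06, estimated-correlation adjusted p = 0.31). Of 15 mesenchymal regulators 10 fell, including N-cadherin Cdh2 (-4.24 ± 0.054) and Zeb2 (-4.14 ± 0.048), and 5 were not called (median -1.66, adjusted p = 1.28e-05, estimated-correlation adjusted p = 0.31). Epithelial junction genes fell too, 16 of 18, with 2 not called (median -1.89, adjusted p = 2.08e-06, estimated-correlation adjusted p = 0.31). In the interferon and MHC class I list 16 of 20 fell, including Psmb8 (-4.45 ± 0.045), and 4 were not called (median -1.86, adjusted p = 6.85e-05, estimated-correlation adjusted p = 0.333). Of 29 imprinted genes 16 fell, including Grb10 (-4.06 ± 0.045), Dcn (-3.39 ± 0.046) and Meg3 (Gtl2, -2.25 ± 0.064). Another 3 rose, including Peg12 (1.71 ± 0.047) and H19 (1.5 ± 0.068), and 10 were not called (median -1.58, adjusted p = 0.00297, estimated-correlation adjusted p = 0.31). Of 33 Hox genes 6 fell, including Hoxb2 (-3.79 ± 0.047; its other probe -0.21), and 27 were not called (median -0.29, adjusted p = 0.0211, estimated-correlation adjusted p = 0.436). The Hox shift lost its call with marked spots kept (median -0.25, adjusted p = 0.167) and with normexp over all spots (median -0.29, adjusted p = 0.127), at nearly the same median. Neuronal genes fell in 5 of 10 cases, including the growth cone gene Gap43 (-3.32 ± 0.057), and 5 were not called (median -1.19, adjusted p = 0.0347, estimated-correlation adjusted p = 0.31). The call of this list was lost with the mean over probes (median -0.61, adjusted p = 0.0702) and with normexp over all spots (median -1.19, adjusted p = 0.0577).

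The remaining lists were not called in iPS over ES cells. Under median centring the primed epiblast (adjusted p = 2.42e-05), lineage (0.000282), brake and cyclin (0.00337), muscle (0.00796) and LIF and BMP (0.0115) lists were called, and the primed epiblast list was also called under other alternatives. Lineage genes had 2 of 25 higher, Tfap2c (2.56 ± 0.060) and Afp, alpha-fetoprotein (1.52 ± 0.051). Another 9 were lower, including T (-4.27 ± 0.063) and the VEGF receptor Kdr (-4.10 ± 0.046), and 14 were not called (list median -0.46, adjusted p = 0.0695). Primed epiblast genes had 6 of 10 lower and 4 not called (median -1.81, adjusted p = 0.0695). The list of cell cycle brakes and D-type cyclins had 1 of 17 higher, the cyclin Ccnd3 (1.35 ± 0.062), 7 lower, including the inhibitor Cdkn2b (-3.52 ± 0.045) and the cyclin Ccnd2 (-3.42 ± 0.070), and 9 not called (median -0.31, adjusted p = 0.162). Glycolysis genes had 2 of 18 higher, including Pfkp (2.19 ± 0.048), 6 lower, including Eno2 (-2.14 ± 0.049), and 10 not called (median -0.34, or 0.12 with median centring; adjusted p = 0.45). The LIF and BMP targets had 2 of 14 higher, including Klf4, 7 lower, including Sp5 (-5.47 ± 0.044), and 5 not called (median -0.79, adjusted p = 0.309). Endothelial markers had 4 of 10 higher, including Robo4 (4.37 ± 0.17), 2 lower, Kdr and Flt1 (-4.80 ± 0.070), and 4 not called (median 0.91, adjusted p = 0.12). Muscle genes had 1 of 13 higher, Myh3 (1.68 ± 0.054), 5 lower, including Acta1 (-4.46 ± 0.047), and 7 not called (median -0.26, adjusted p = 0.254).

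Macrophage markers had 1 of 14 higher, Laptm5 (1.53 ± 0.048), 2 lower, including Aif1 (-1.36 ± 0.060), and 11 not called (median -0.019, or 0.14 with the processed signals; adjusted p = 0.915). Sex-linked genes had 1 of 7 higher, Kdm5d (at least 2.31-fold), and 6 not called (median 0.44, adjusted p = 0.213). Housekeeping genes had 2 of 13 lower, B2m and Ywhaz (-2.78), and 11 not called (median -0.29, or 0.20 with median centring; adjusted p = 0.12). Over all genes, 1568 were higher and 2056 lower in iPS than in ES cells, together 21.0% of those tested, and 13789 (79.96%) had an adjusted p under 0.05 at any fold. The share of higher calls was 43.3%, and 62.4% with median centring, and with the processed signals 2979 genes were higher. Among genes well above background in both channels of all 4 arrays, the shifts of the germ cell (adjusted p = 0.18), 2-cell stage (0.156) and neuronal (0.279) lists were not called. Their medians were then 1.54, 1.15 and -0.91. This filter drops the members that are dim in any of the cell types, such as Dazl.

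**Figure D2:**
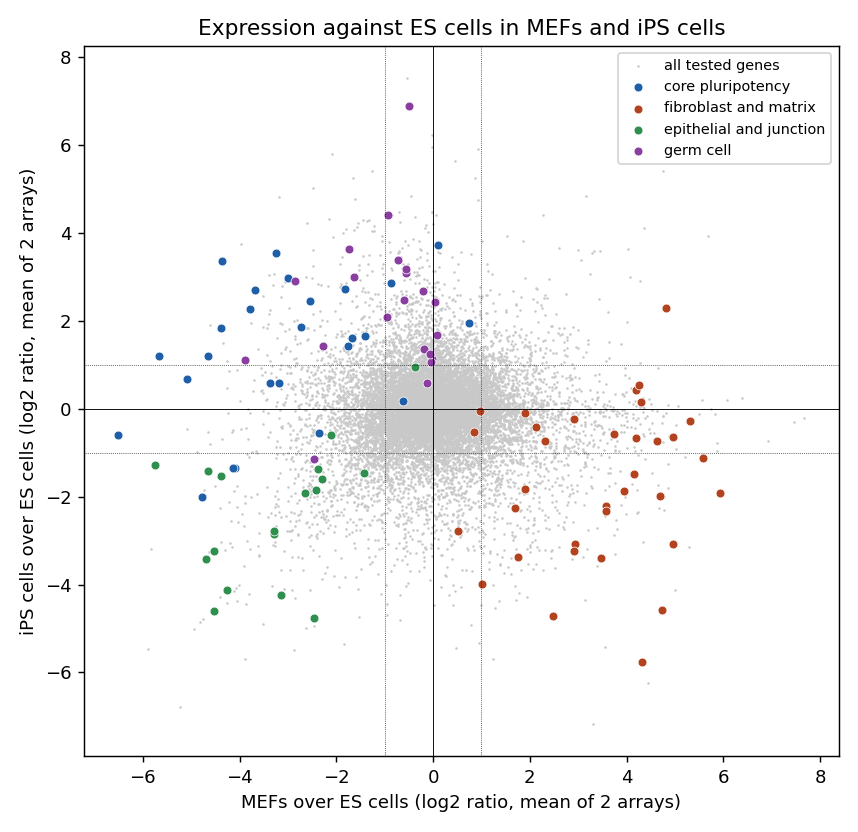
Log2 ratio of iPS cells over ES cells (vertical axis) against MEFs over ES cells (horizontal axis) for the 17244 genes tested, each the mean of 2 arrays. Across genes the ratios correlated at 0.0192, and 598 genes were lower than in ES cells in both comparisons.

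In iPS cells compared with MEFs, most measured pluripotency (25 of 26), germ cell (20 of 21) and cell cycle genes (23 of 28) were higher. All 34 fibroblast matrix genes measured and 21 of 33 Hox genes were lower. Nanog stood at 6.06 ± 0.065, Sox2 at 5.84 ± 0.068, Cdh1 at 4.47 ± 0.081 and Pou5f1 at 2.74 ± 0.11. Col1a1 fell to -10.09 ± 0.063, Col1a2 to -9.31 ± 0.062 and Thy1 to -3.77 ± 0.079, and Cav1 was at least 1344-fold lower. Aqp3, a water and glycerol channel, rose by 7.99 ± 0.071. Cdkn2a fell to -2.29 ± 0.26, and Xist was lower and not well above background in iPS cells.

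The other largest rises were Nr0b1, an orphan nuclear receptor (at least 202-fold), Tex19.1 (7.70 ± 0.092), Stra8, a gene of meiotic entry (7.52 ± 0.091), and Khdc3 and Dazl, both not well above background in MEFs. The other largest falls were Prss23 (-10.48 ± 0.063), Col8a1 (-9.12 ± 0.089) and the matrix gene Efemp1 (-8.96 ± 0.071). Dppa3 (6.39 ± 0.063), Esrrb (5.97 ± 0.064), Zfp42 (5.90 ± 0.092) and Klf4 (1.19 ± 0.062) rose, and Myc (-1.58 ± 0.066) and Meg3 (Gtl2, -2.08 ± 0.091) fell. Other probes were milder for Col1a2 (-0.62), Prss23 (-2.48), Cav1 (-4.20), Col8a1 (-6.82) and Col1a1 (-6.47 and -3.85).

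Of 26 core pluripotency genes 25 rose, including Tdh (6.88 ± 0.085), and Fut9 (0.80) was not called (median 4.24, camera adjusted p = 1.71e-10, estimated-correlation adjusted p = 0.31). All 34 fibroblast matrix genes measured fell (median -5.24, adjusted p = 3.62e-13, estimated-correlation adjusted p = 0.31). Mesenchymal regulators fell in 14 of 15 cases, including Twist2 (at least 84.2-fold) and Prrx1, not well above background in iPS cells, and Runx1 (-0.43) was not called (median -4.59, adjusted p = 6.81e-07, estimated-correlation adjusted p = 0.31). Epithelial junction genes rose in 8 of 18 cases, including Epcam (3.22 ± 0.11), fell for Krt19 (-2.30 ± 0.083) and Dsp (-1.08 ± 0.073), and were not called in 8 (median 0.72, adjusted p = 0.0156, estimated-correlation adjusted p = 0.455). Germ cell genes rose in 20 of 21 cases and 1 was not called (median 3.08, adjusted p = 6.38e-08, estimated-correlation adjusted p = 0.31). Cell cycle genes rose in 23 of 28 cases, including Mcm2 (2.95 ± 0.062) and Mcm7 (2.82 ± 0.061), and 5 were not called (median 1.91, adjusted p = 4.37e-08, estimated-correlation adjusted p = 0.31).

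Chromatin regulators rose in 16 of 20 cases, including Dnmt3l (6.52 ± 0.11) and Dnmt3b (5.09 ± 0.068), and 4 were not called (median 2.09, adjusted p = 3.94e-06, estimated-correlation adjusted p = 0.31). Hox genes fell in 21 of 33 cases, including Hoxc9 (-4.92 ± 0.062) and Hoxb6 (-4.73 ± 0.10), and 12 were not called (median -1.51, adjusted p = 3.18e-05, estimated-correlation adjusted p = 0.31). In the list of cell cycle brakes and D-type cyclins 10 of 17 fell, including the inhibitor Cdkn2b (-4.91) and the cyclins Ccnd2 (-6.28 ± 0.099) and Ccnd1 (-2.77), and 1 rose, Trp53 (1.49 ± 0.099), while 6 were not called (median -1.57, adjusted p = 0.00331, estimated-correlation adjusted p = 0.31). Of 29 imprinted genes 15 fell, including Dcn (-6.87 ± 0.065) and Igf2 (-6.38 ± 0.097). Mest (1.56 ± 0.062) and Snrpn (1.28 ± 0.064) rose, and 12 were not called (median -1.06, adjusted p = 0.00901, estimated-correlation adjusted p = 0.31). Muscle genes fell in 8 of 13 cases, including Actc1 (-5.67 ± 0.090), and 5 were not called (median -1.75, adjusted p = 0.00351, estimated-correlation adjusted p = 0.31). Macrophage markers fell in 4 of 14 cases, including Lyz2, not well above background in iPS cells (its other probe -0.57), Laptm5 rose (2.45 ± 0.067), and 9 were not called (median -0.70, adjusted p = 0.0358, estimated-correlation adjusted p = 0.31). In the interferon and MHC class I list 7 of 20 fell, including B2m (-5.27 ± 0.063), 2 rose, including Oas1a (1.31 ± 0.066), and 11 were not called (median -0.80, adjusted p = 0.00472, estimated-correlation adjusted p = 0.436).

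The 2-cell stage list had 7 of 9 higher, including Zscan4c (at least 113-fold), Tdpoz1 lower (-1.13 ± 0.11) and 1 not called (median 2.14, adjusted p = 0.0204, estimated-correlation adjusted p = 0.31). Primed epiblast genes had 5 of 10 higher, including Dnmt3b, Fgf5 lower (-2.33 ± 0.078) and 4 not called (median 1.06, adjusted p = 0.049, estimated-correlation adjusted p = 0.459). Lineage genes had 5 of 25 higher, including Tfap2c (6.07 ± 0.084) and Sox17 (at least 3.78-fold). Another 7 were lower, including Zic1 (-6.11 ± 0.15) and Nes, nestin (-4.33 ± 0.083), and 13 were not called, with a median of 0.14 (-0.28 with marked spots kept or normexp over all spots) and a mean of -0.28, of opposite sign (adjusted p = 0.955). Endothelial markers had 5 of 10 higher, including Robo4 (4.75 ± 0.24), 3 lower, including Emcn, not well above background in iPS cells, and 2 not called (median 0.95, adjusted p = 0.571). Glycolysis genes had 5 of 18 higher, including Hk2 (1.41 ± 0.077), 5 lower, including Eno2 (-3.30 ± 0.069), and 8 not called (median -0.34, or 0.083 with normexp over all spots; adjusted p = 0.463). The LIF and BMP targets had 2 of 14 higher, including Gbx2 (2.72 ± 0.065), 7 lower, including Junb (-2.58 ± 0.066), and 5 not called (median -0.65, adjusted p = 0.549). Neuronal genes had 3 of 10 higher, including Nefl (2.63 ± 0.089), 3 lower, including Gap43 (-3.50 ± 0.080), and 4 not called (median -0.042, or 0.033 with quantile normalization; adjusted p = 0.901).

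Sex-linked genes had 2 of 7 higher in iPS cells than MEFs, including Ddx3y (1.59 ± 0.065), Xist lower and 4 not called (median 0.84, adjusted p = 0.162). Housekeeping genes had 1 of 13 higher, Tbp (1.29 ± 0.073), 5 lower, including B2m, and 7 not called, with a median of 0.024 (-0.021 with the processed signals) and a mean of -0.71 (adjusted p = 0.49). In all, 2935 genes were higher and 3291 lower, together 36.1% of those tested, and 13992 (81.1%) had an adjusted p under 0.05 at any fold. With normexp fitted over all spots the counts were 1047 and 1192, and with the processed signals 4686 genes were higher. The primed epiblast shift lost its call under most other background corrections and normalizations. Its median was then 1.17 with quantile normalization, 1.22 with no background correction and 2.25 with the processed signals. It was smaller with marked spots kept (0.55) and with normexp over all spots (0.39). The macrophage shift lost its call with the mean over probes (adjusted p = 0.051), median centring (0.143), normexp over all spots (0.242) and marked spots kept (0.25). Among genes well above background in both channels of all 4 arrays, the epithelial junction (adjusted p = 0.165), primed epiblast (0.182), 2-cell stage (0.792) and macrophage (0.834) shifts were not called. Their medians were then 0.57, 1.06, 1.575 and -0.20. The epithelial junction median turned to -0.15 with normexp over all spots and with marked spots kept.

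**Figure D3:**
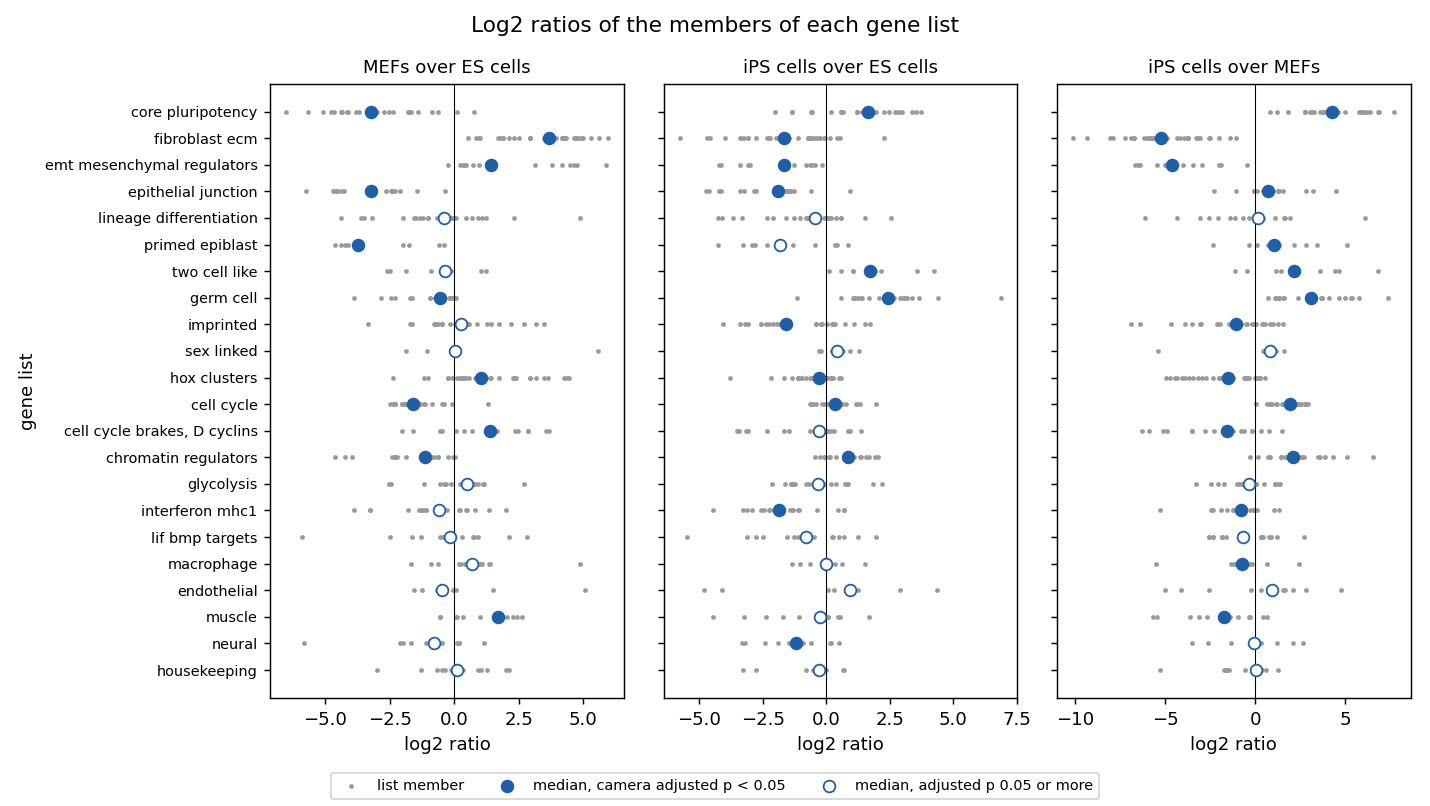
Log2 ratios of the measured members of the 22 gene lists (grey points) and the median of each list (circles, filled where the camera adjusted p was under 0.05) in MEFs over ES cells, iPS cells over ES cells and iPS cells over MEFs. The fibroblast matrix median lies at 3.66, -1.65 and -5.24 and the germ cell median at -0.56, 2.41 and 3.08.

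Genes that set MEFs apart from ES cells were then followed in iPS cells. The 2413 genes higher in MEFs had a median of 1.59 in MEFs over ES cells and -0.12 in iPS over ES cells (-0.14 and -0.13 on the separate iPS arrays). Of these, 250 (10.4%) were also higher in iPS cells, Thumpd1 and Ddr2 among them, 459 (19.02%) were lower, Col1a1 and Cav1 among them, and 1704 (70.6%) were not called. The 2363 genes lower in MEFs had medians of -1.51 and -0.22 (-0.23 and -0.21 on the separate iPS arrays). Among them 598 (25.3%) were also lower in iPS cells, including Sp5, Gbp3 and T, 310 (13.1%) were higher, including Nanog and Esrrb, and 1455 (61.6%) were not called. The 1397 tested genes of chromosome 11, Col1a1 and the Hoxb genes among them, had medians of -0.27 in MEFs and -0.20 in iPS cells over ES cells. Both iPS medians of the genes called in MEFs turned above 0 with median centring, at 0.050 and 0.039. Across genes, green and red intensities of an array correlated at 0.8999 and 0.8985 for MEFs and at 0.923 and 0.921 for iPS cells, where genes are not independent replicates.

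Both comparisons are ratios over ES cells, so their calls can overlap where the ES RNA is shared. Independent lists of these sizes would share 219 higher and 282 lower genes, against 250 and 598 observed, and 20 simulations without any effect gave 2.8 and 2.6. The count for independent lists takes every gene as equally likely to be called. Ratios of dim genes spread less, with a standard deviation in MEFs of 0.49 in the dimmest of 5 intensity bins and 1.08 in the brightest (chromosome 11 apart). Some excess can therefore arise in every direction, opposite calls included. With median centring 599 higher and 389 lower genes were shared, against 539 and 142 for independent lists. Opposite calls numbered 459 (higher in MEFs, lower in iPS cells) and 310 (the reverse), against 288 and 215 for independent lists. The correlation of the ratios was 0.0192 against 0.674 in the simulations, and the covariance 0.0219 against 0.00981. The simulated correlation is that of noise alone, so it is no measure for the observed one. Each array carries its own ES channel, but whether the ES RNA came from separate cultures is not stated. Part of the excess in the same direction may therefore come from shared controls. A gene-specific dye effect stays in both ratios over ES cells and could add to it, which was not tested. Shared controls would move both ratios the same way and do not account for the excess of opposite calls.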

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

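The spike-in control probes, which the comparisons do not use, gave signals far above the negative controls in both channels and unequal between them. Over 10 probes (320 spots), the median log2 ratio of red over green was 2.69 on the array of MEF replicate 1, 3.46 on that of MEF replicate 2, 2.73 on that of iPS replicate 1 and 2.76 on that of iPS replicate 2. The median red signals were 14750, 19550, 10900 and 12200, against 52.4 to 54 for negative controls, and the median green signals 1145 to 1205, against 17.2 to 18.7. Per the file headers, the scanner software's fits of observed on expected spike-in log10 ratios had slopes of 0.888, 0.875, 0.883 and 0.893, intercepts of 0.789, 0.986, 0.803 and 0.822, and correlations of 0.973, 0.969, 0.963 and 0.963. With 2 arrays per group, no array was tested for standing apart from its group.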

How the results depend on the processing

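The adopted fit of normexp over unmarked spots, that over all spots, the fit leaving out only spots with a local background above 500, the crossed pairing and the fit without chromosome 11 were chosen after seeing the data. Leaving out only those spots gave 2392 higher and 2335 lower genes in MEFs over ES cells, 1564 and 2050 in iPS over ES cells and 2911 and 3263 in iPS cells over MEFs. Without chromosome 11 genes the counts were 2307 and 2068, 1485 and 1809, and 2691 and 3061. Over ES cells the fall was uneven, because 295 of its genes were lower and 106 higher in MEFs, and 247 and 83 in iPS cells. The share of higher calls rose from 50.5% to 52.7% in MEFs and from 43.3% to 45.1% in iPS cells over ES cells. Of 66 list shifts, 35 kept their direction and side of the threshold under every alternative run (36 apart from normexp over all spots), and of 199 gene values 80 did (85 likewise). None of the called genes set by the naming rule turned its direction; further examples were not run. The list of epithelial junctions in iPS cells over MEFs turned to -0.15 with marked spots kept and with normexp over all spots. Leaving out each replicate gave 2370 to 2467 higher and 2363 to 2408 lower genes in MEFs over ES cells, 1552 to 1588 and 2037 to 2086 in iPS over ES cells, and 2916 to 2961 and 3285 to 3326 in iPS cells over MEFs, a lone array taken to vary like the other group. The iPS median of genes higher in MEFs then ranged from -0.135 to -0.105.

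With normexp over all spots, 35 genes were higher and 25 lower in MEFs over ES cells, 1174 and 1407 in iPS over ES cells, and 1047 and 1192 in iPS cells over MEFs. The iPS medians of genes higher and lower in MEFs were then -1.26 and -0.54, with 2 and 10 genes called the same way in iPS cells. Of the 199 gene values 114 lost their call there, and 109 with marked spots kept; none did when only the spots with a background above 500 were left out. With marked spots kept, 153 and 135 genes were called in MEFs and 1167 and 1366 in iPS cells over MEFs, with medians of -0.58 and -0.43 and 12 and 36 shared calls. Both settings let the 14 spots with a background defect into the fit. With the processed signals, 3866 genes were lower in MEFs, 2979 higher in iPS than ES cells and 4686 higher in iPS cells than MEFs, with medians of -0.020 and -0.049 and 644 and 964 shared calls. The series' value table gave 3863, 2970 and 4688, medians of 0 and -0.050, and 643 and 963. With median centring, 1573 genes were lower in MEFs and 2582 higher in iPS than ES cells, with medians of 0.050 and 0.039 and 599 and 389 shared calls. Median centring moved the median of all genes to 0.18 in MEFs and 0.17 in iPS cells over ES cells, and the processed signals, quantile normalization and the red channel alone moved it to 0.15, 0.12 and 0.12 in iPS cells over MEFs. A normexp offset of 0 gave medians of -0.128 and -0.158 and 441 shared calls in genes higher in MEFs. Quantile normalization gave medians of -0.099 and -0.175. The stricter filter on dim probes gave -0.11 for genes higher in MEFs, and the mean over probes -0.245 for genes lower in MEFs. Without a fold limit 7065 and 7361, 6843 and 6946, and 7127 and 6865 genes were called, since the fold limit removes the small changes. Genes called at 4-fold or more had medians of -0.27 and -0.51. The cause of the other differences was not tested.

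Apart from marked spots kept and normexp over all spots, calls of genes set by the rule and named in the text ended for Tdrd1 with median centring, for Dsp with quantile normalization and with the red channel alone, and with the mean over probes for Map2, Aif1, Trp53 and Dsp. Without iPS replicate 1 Tdpoz1 lost its call in iPS cells over MEFs (-0.97).

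In MEFs over ES cells, the neuronal (adjusted p = 0.00337), lineage (0.018), interferon (0.0264) and 2-cell stage (0.046) lists gained calls with median centring. The macrophage list gained one with no background correction (0.0365), the processed signals (0.0259), the series' value table (0.026), quantile normalization (0.0294) and without iPS replicate 1 (0.0482) or 2 (0.0494). In iPS over ES cells, 5 lists gained calls with median centring, and the primed epiblast list also with no filter on dim probes (0.0126), the stricter filter (0.0147), marked spots kept (0.047) and without iPS replicate 1 (0.0324) or 2 (0.0312). The lineage list gained one with no filter (0.0144) and without iPS replicate 1 (0.0324), housekeeping with no filter (0.0485) and the brake and cyclin list with marked spots kept (0.0315). In iPS cells over MEFs, the primed epiblast call ended under 10 settings (0.0523 to 0.946), with medians from 0.39 to 2.25. Among them was the fit without MEF replicate 1 (median 1.05). Sex-linked genes gained a call there with marked spots kept (0.0452).

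Whether the replicate numbers pair the samples cannot be told from 2 pairs. The correlation of deviations was -0.12 (Spearman -0.070). With the number as a block, 1567 genes were higher in iPS than ES cells, the other counts were the same, and the macrophage list in MEFs gained its call (adjusted p = 0.0494). The crossed pairing gave 2413 and 2363, 1568 and 2056, and 2935 and 3292. Signal over background limits the ratios of dim genes: 398, 292 and 914 called genes had a group not well above background.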

Other observations

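The tests below were chosen after the patterns were seen. Those of GC content, of intensity over 5 bins, of an extra copy over all genes and of cross-hybridization had their bounds set before their own results were seen, from a look at brighter genes in the case of chromosome 11, and the tests for brighter genes, dye bias, DNA methylation genes and MEF RNA were chosen after their results were seen.

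Genes of chromosome 11 were lower than in ES cells in both other cell types. Over its 1397 tested genes the median log2 ratio was -0.27 in MEFs and -0.20 in iPS cells over ES cells, and 0.064 in iPS cells over MEFs. No random set (0 of 10000, matched on intensity) was as low in either comparison over ES cells, where the lowest were -0.086 and -0.056. In MEFs 295 chromosome 11 genes were lower and 106 higher, and in iPS cells 247 and 83. Other chromosomes differed from the rest of the autosomes by less in the ratios over ES cells, the largest being chromosome 17 in iPS cells (0.17), chromosome 19 in MEFs (0.16) and chromosome X in iPS cells (-0.12).

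Probe GC content is argued against, since the higher of the medians stayed at -0.227 after its removal; the bound of -0.3 set beforehand lay beyond the unadjusted medians, so the medians were set against the lowest random sets instead, a criterion added later. An intensity effect left by the normalization met the bound set for it over 5 bins. The difference from other autosomes was -0.036 in iPS cells in the dimmest bin, where the other autosomes also spread least, and -0.092 in the next bin (-0.29 there in MEFs). Over all 1397 genes the random sets matched on intensity argue against it, since the lowest were -0.086 and -0.056 against medians of -0.27 and -0.20. Differences in the dimmest bin are too small to decide anything for its genes. In the 3 brighter bins the intensity effect is also argued against, with every difference at -0.36 or lower. An extra copy of chromosome 11 in the ES line may contribute: among the 873 brighter genes all 12 segment medians lay at least 0.2 below the other autosomes (-0.27 the highest), and 3 copies would give -0.585. Over all genes 8 of 12 segments did (-0.14 the highest), which leaves it open, and DNA copy number was not measured.

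Germ cell genes were higher in iPS than in ES cells (19 of 21). Lower transcripts of the DNA methylation machinery are argued against, since Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l and Uhrf1 had a median of 1.32 in iPS over ES cells. A cross-hybridizing probe could account for single genes and stays open, because only 2 other tested probes exist and 50% of them, Taf7l (3.04) but not Mov10l1 (0.52), reached 2-fold. A gene-specific dye effect stays open too: the median of these 19 genes in MEFs with the same dye (-0.56) cannot exclude it, because the list is itself lower in MEFs. A difference between the clone and the ES line stays open and was not tested.

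Fibroblast matrix genes were lower in iPS than in ES cells (19 of 34), though MEFs were far above both. RNA with the profile of these MEFs in the ES sample is argued against as the cause of the list's fall: the median share needed (6.74%) was 3.95 times the highest share (1.71%) that 5 bright genes outside the list allow, the lowest being 0.491% for Cavin2. Even the highest of these shares, 1.71%, would cover the full fall of only Col5a2 and Lox (17 of 19 need more). The shares that Cavin2, Tm4sf1 (0.565%) and Fibin (0.830%) allow lie under every need, while those of Thbd and Prrx1 do not. The needs ran from 1.13% (Col5a2) to 59.7% (Ccn1), a 52.7-fold range against a single share as the whole cause. A gene-specific dye effect stays open, because the median of the 19 genes in MEFs with the same dye (3.57) is set by their expression there and could hide it, and the shares above hold only apart from such effects. Feeder RNA with another profile and differentiated cells in the ES culture stay open and were not tested.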
